A study of Dreissena polymorpha with 11 samples.

How the data were processed

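The series holds 11 arrays of the zebra mussel Dreissena polymorpha, a freshwater bivalve, hybridised with total RNA from untreated animals. Per the labels, RNA was extracted with Trizol, treated with DNase, checked on a Bioanalyzer and labelled with the dye Cy3, starting from 500 ng for tissues and 200 ng for larvae. Each array carried 15208 spots other than controls, which held 13654 distinct probes made for 3541 sequences. Of these probes, 12606 had 1 spot, 1026 had 2 spots and 22 had 25 spots.

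The scanner files give intensity values per spot, and per the file headers they were made with Agilent Feature Extraction 10.5.1.1, which subtracted the background and removed spatial trends within each array, and did not scale arrays to each other. A value table of log2 values that the authors deposited has 14519 rows and 35 missing values. How that table was scaled and centred is not given in the sources used here. Set against the scanner values of the same array across probes, 9 of its 11 columns had Pearson r between 0.984 and 0.991, with column medians between 2.97 and 3.24. The columns of larvae replicate 1 and gill replicate 1 had r of 0.28 and 0.579, with medians of 3.52 and 4.23. The table was therefore used only as an alternative. The column of gill replicate 1 is part of every fit of all groups on that table. Whether it lowers the counts of calls there was not tested.

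Groups were taken from the labels. They are larvae at 24 h (2 arrays), gill (2), digestive gland (2), male gonad (2), female gonad (1) and half-body samples (2). Nothing in the labels says whether samples of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The gender label gives 1 female and 1 male array in gill, digestive gland and half-body samples, whereas another label calls all gill and digestive gland samples female. The arrays lay on 3 slides, each with its own scan day. Slide 1 held larvae 1, digestive gland 1, male gonad 1 and half-body 1. Slide 3 held gill 1 alone, and slide 2 held the other 6 arrays, with 1 array of every group. The titles of both half-body samples carry the number 1, so half-body 1 and 2 are numbered here in the order of the samples. In digestive gland and half-body samples the labelled sex follows the slide exactly, and in gill it does as well.

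The design fixed before the data were examined used all 11 arrays. Spots flagged as outliers and control spots were left out, log2 of the processed signal was reduced by the array's 75th percentile over all probes, and spots of 1 probe were averaged. Probes were tested if they were well above background, by the scanner software's own call, on all arrays of at least 1 group. A group-means model was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment, and a probe was called at an adjusted p below 0.05. A probe not well above background on every array of 1 side has only a bound there, given as "at least N-fold": the bright side's mean log2 value against, on each dim array, the higher of the probe's own value and the lowest value among probes well above background. Where only some arrays of the dim side, with a whole group among them, are not well above background, those arrays are treated in the same way and the others keep their values.

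Larvae replicate 1 turned out to have 106 probes well above background, against 4357 to 5631 on each of the other arrays. A fit on the 10 other arrays was therefore added after the data had been seen. In it, the 75th percentile is taken over the 3075 probes well above background on all 10 arrays, since no array had more than 5631 of 13654 probes detected; this leaves larvae and female gonad with 1 array each, assumed to vary like the other groups. It was adopted after the call counts of several settings had been viewed, among them quantile normalization, the percentile over all probes, stricter and wider probe filters and medians per sequence, and every one of those counts is given with the dependence on the processing. Its calls are a description chosen on these data and do not replace the fixed fit, whose count is printed beside each one. In each contrast of the fixed fit, 268.9 of 5378 probes would have an unadjusted p under 0.05 by chance. A contrast with fewer such probes and 0 calls does not show that its groups are alike.

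The files name sequences by identifiers and pair none of them with a gene, apart from the symbol RXR for 6 probes. None of the 3541 sequence names matched the 51549 genes of the RefSeq table of assembly UMN_Dpol_1.0, and none matched any of the 24 gene lists fixed beforehand, so no gene list test was run. Probes are named by their IDs. For each contrast the rule fixed beforehand names up to 2 called probes that were higher and 2 that were lower, 1 per sequence, with the largest log2 difference among those well above background on all arrays of at least 1 group of the higher side and with every array of one side beyond every array of the other. Sequences were also grouped by the letters that begin their identifiers (EY, AM, AJ and others), a grouping made after the data had been seen. Enrichment of a series among called sequences was tested with the two-sided Fisher's exact test, adjusted over 36 tests, against the sequences tested in the same comparison. Probes of 1 sequence are not independent, and a sequence counts once. It counts as called if any of its probes is called, so sequences with more tested probes have more chances. AJ had 439 tested probes for 127 sequences and EY 4240 for 1916, and the test does not correct for this. A series was also tested with only the probes detected on all arrays of a group other than the one compared, since a probe detected in that group alone enters the test because it is high there. The calls counted there are those of the fit on all tested probes, with its adjustment.

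The fit was tested on simulated arrays in which 200 probes were shifted by known amounts. For gill against other tissues, the 11-array fit called 8% of the probes shifted by 4 log2 units and 64% of those shifted by 8, among 5318 probes, and the 10-array fit called 62% and 86% among 5853. Of its simulated gill calls, 8.2% were false in the 11-array fit and 7.52% in the 10-array fit. Such shares, here and for larvae below, describe the simulated arrays only. On the real arrays, differences between replicates correlated across probes at 0.73 for digestive gland with male gonad and 0.01 for gill with either. Whether such shared deviations change the share of false calls was not tested. For larvae against adult tissues, the 11-array fit called 14% of the probes shifted by 4 log2 units and 80% of those shifted by 8, and the 10-array fit 46% and 76%, with 9.877% and 6.481% of simulated calls false.

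Alternatives tried were other background corrections (normexp with an offset of 50, on the median signal because the files lack the mean signal planned for it), scalings, probe filters, the deposited table, fits on fewer groups, replicate number, slide and sex as terms, trend and robust variances, stricter thresholds and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads, a genome and gene names for the probes were not used here. The number of arrays, 10 or 11, limits the precision of every value.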

Results

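The study set out to describe how gene expression differs between tissues of untreated zebra mussels and their larvae. Signal was measured on 11 single-dye arrays in 6 groups, namely larvae at 24 h, gill, digestive gland, male gonad and half-body samples with 2 arrays each and female gonad with 1. The arrays detected between 4357 and 5631 of the 13654 probes well above background, except larvae 1, on which 106 probes passed and the highest signal of any spot was 125.4. Adult arrays with the most detected probes were male gonad 2 with 5631, digestive gland 2 with 5318 and half-body 2 with 5247. The spread between duplicate spots of a probe, as the SD of the log2 difference, ran from 0.47 on female gonad 1 to 1.19 on larvae 2.

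**Figure D1:**
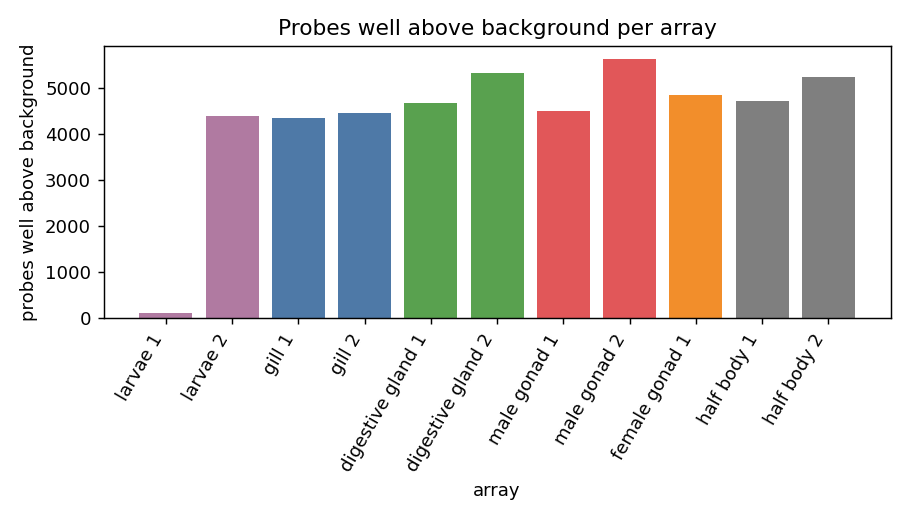
Bars give the number of probes well above background (vertical axis) on each of the 11 arrays (horizontal axis), coloured by group. Larvae 1 reached 106 probes, and the other arrays lay between 4357 and 5631.

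Across the 5853 probes with values on the 10 arrays other than larvae 1, the pair of gill arrays correlated with Pearson r = 0.956, and either gill array with the other adult arrays at 0.776 to 0.91. With AM probes left out (identifiers beginning with AM), gill correlated with the other adult arrays at 0.907 to 0.927, while those arrays correlated with each other at 0.941 to 0.982. Half-body arrays correlated at 0.956 with each other. Digestive gland 1 and 2 correlated at only 0.899 and male gonad 1 and 2 at 0.877, whereas digestive gland 1 correlated with male gonad 1 at 0.965 and digestive gland 2 with male gonad 2 at 0.97. Larvae 2 had its highest correlation with gill 2, at 0.894, and its lowest with male gonad 2, at 0.729. Without AM probes this order turned, with the highest values at digestive gland 1 and female gonad 1 (0.894 each), the lowest at gill 1 (0.871), and male gonad 2 at 0.877. These correlations are across probes, which are not independent replicates.

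**Figure D2:**
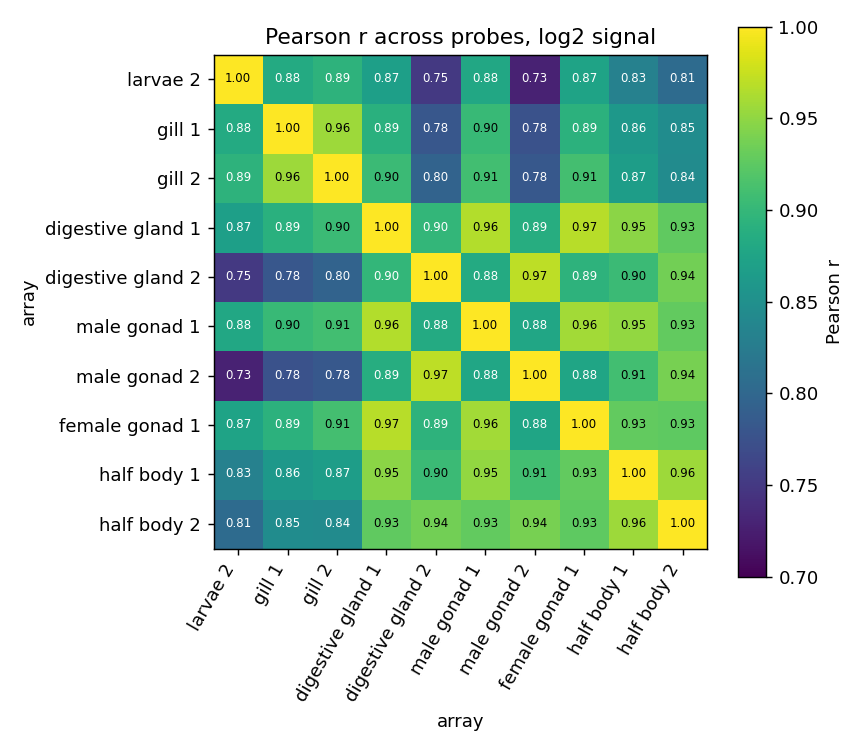
Each cell gives Pearson r across probes between the log2 signals of 2 arrays, listed on both axes. Digestive gland 2 and male gonad 2 form a pair at 0.97, above the 0.899 of digestive gland 2 with digestive gland 1.

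AM probes differed more than EY probes within the digestive gland pair and within the male gonad pair. Over the 1075 AM probes that passed the detection filter, the median log2 signal relative to the array's 75th percentile of common probes was -4.63 on digestive gland 2 and -4.33 on male gonad 2. It was -9.32 on digestive gland 1, -10.06 on male gonad 1, -9.2 on female gonad 1, -7.85 on half-body 1 and -6.4 on half-body 2. Gill 1, gill 2 and larvae 2 had medians of -11.78, -10.74 and -11.03. Taken probe by probe, male gonad 2 exceeded male gonad 1 by a median of 5.36 (quartiles 0.47 and 7.06) and digestive gland 2 exceeded digestive gland 1 by 2.68 (quartiles -0.46 and 6.07). The 4255 EY probes differed by medians of 0.25 and 0.07 in those pairs. With AM probes left out, the digestive gland pair correlated at 0.964 and the male gonad pair at 0.961, still below digestive gland 2 with male gonad 2 at 0.982 and digestive gland 1 with male gonad 1 at 0.968. Within AM probes alone the pairs correlated at 0.594 and 0.579. Across the groups, AM probes correlated at 0.948 between digestive gland 1 and male gonad 1 and at 0.885 between digestive gland 2 and male gonad 2.

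**Figure D3:**
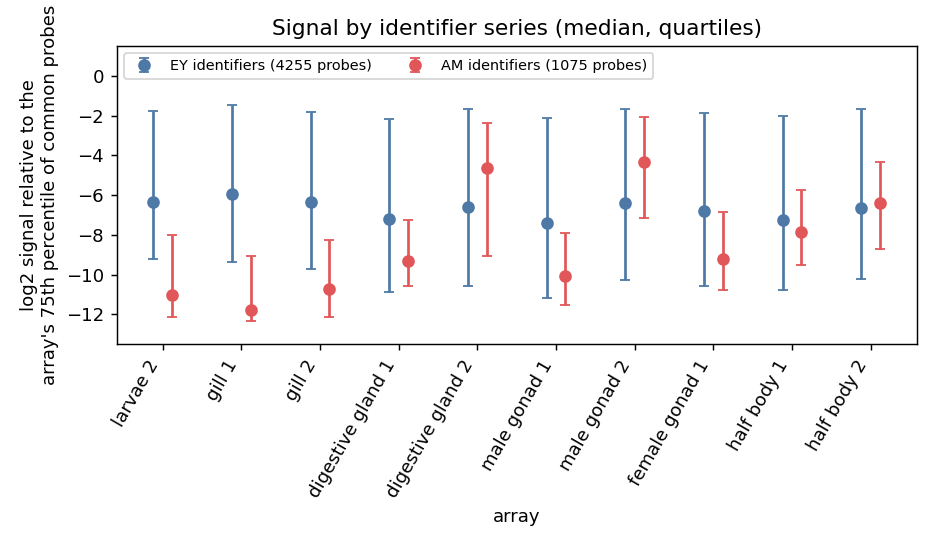
Points give the median log2 signal (vertical axis, relative to each array's 75th percentile of common probes) of the EY and AM probes on each of 10 arrays (horizontal axis), and bars the quartiles. AM medians lie between -11.78 on gill 1 and -4.33 on male gonad 2, while EY medians lie between -7.38 and -5.94.

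Gill was compared with digestive gland and both gonads. In the fit on 11 arrays fixed beforehand, limma called 52 of 5378 probes, 1 higher and 51 lower in gill. In the fit on 10 arrays, chosen after the data had been seen, it called 234 of 5910 probes, 139 higher and 95 lower, and 51 of the 52 were among them with the same sign. Of these calls, 89 higher and 95 lower lay among the 5822 probes detected on all arrays of a group other than gill. These are calls of the fit on all 5910 probes, not of a new fit. The 10-array lower calls came from 33 sequences, of which 11 were AJ, a share of 33.3% against 5.06% of the sequences tested (Fisher's exact test, adjusted p = 1.63e-06, and 1.1e-05 with only the probes detected in a group other than gill). AJ was not the only series to differ. EY made up 96% of the sequences with higher calls and 36.36% of those with lower calls, against 76.37% of those tested. For AM these shares were 2% and 27.27%, against 16.1%. Over all AJ probes that passed the filter, the median was -7.68 on gill 1 and -6.9 on gill 2, against -6.9 to -6.44 on the other adult arrays, and 68.71% and 73.24% were well above background, against 79.59% to 92.29%. Probe CUST_3943_PI415929191 was not well above background on either gill array and was at least 1910-fold higher in the other tissues (limma adjusted p = 0.00036). Its estimate nearest 0 over the other settings was -6.246 log2 units, smaller in size than that bound. The next probe, CUST_9957_PI415929191, is an AM probe, a series with medians of -11.78 on gill 1 and -10.74 on gill 2. Probe CUST_9957_PI415929191 was lower in gill by a log2 difference of -11.22 ± 0.49 (SE, limma adjusted p = 0.00036), and its 3 other probes were all called lower. Higher in gill were probe CUST_6036_PI415929191, at least 82.3-fold (limma adjusted p = 0.041), and probe CUST_4208_PI415929191, at least 50.3-fold (limma adjusted p = 0.0289), both well above background on only 2 of the 5 arrays of the other tissues and not in female gonad. The 2 other probes of the sequence of CUST_6036_PI415929191 had the same sign but were not called. None of the 4 other probes of the sequence of CUST_4208_PI415929191 passed the filter, so its call rests on that probe alone. CUST_6036_PI415929191 was not called under 13 of 26 other settings, with an estimate as low as 3.672 log2 units in the deposited value table, which turned the sign of CUST_4208_PI415929191. The gill 1 column of that table had r = 0.579 with its own scanner values. CUST_4208_PI415929191 also lost its call, with the sign kept, under 10 further settings of the 26. In the fixed fit, CUST_3943_PI415929191 was at least 1660-fold higher in the other tissues (limma adjusted p = 0.00984), CUST_9957_PI415929191 was lower in gill by -11.03 ± 1.83 (limma adjusted p = 0.019), and the single higher probe was CUST_7285_PI415929191, by 6.06 ± 1.14 (limma adjusted p = 0.0358), a call lost under 17 of 24 other settings. On slide 2, which holds 1 array of each group, 233 of the 234 calls had the same sign, although those arrays helped to make the calls, so this is no separate check of slide. Gill 1 is alone on slide 3, so a slide term leaves gill 2 alone to set the gill level. The fixed count of 52 fell to 0 without either gill array and to 0 with the slide as a block, where the 10-array count was 103, with 37 higher and 66 lower. Leaving out larvae 1 or larvae 2 gave 121 and 133 in the fixed fit, and the 10-array count was 128 without male gonad 1, 129 without half-body 1 and 135 without half-body 2. With the 75th percentile over all probes the 10-array split was 48 higher and 73 lower, with each array's median it was 58 higher and 143 lower, and the deposited table gave 10 calls, all lower.

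Digestive gland was compared with gill and both gonads. The fixed fit called 0 of 5378 probes with limma, with 90 at an unadjusted p under 0.05, where 268.9 would be expected by chance. The median SE of this contrast was 1.472 in that fit, which holds the blank larvae 1 array, and 0.58 on 10 arrays. These fits also scale the arrays differently. On 10 arrays 23 probes from 12 sequences were called, all higher, and all 23 were among the 95 probes called lower in gill. All 23 had the same sign on slide 2, whose arrays took part in the fit. Probe CUST_195_PI415929191 was at least 29-fold higher (limma adjusted p = 0.0222), and 3 of its 4 other probes were called higher too. Its mean relative log2 signal was 1.03 ± 0.44 (SD, n = 2) in digestive gland, -0.49 ± 0.15 (n = 2) in male gonad, -0.63 in female gonad and 1.18 ± 0.53 (n = 2) in half-body samples, and it was not well above background in gill, at -10.66. Probe CUST_3943_PI415929191 was at least 25.9-fold higher (limma adjusted p = 0.0394), with means of 1.34 in digestive gland, 0.31 in male gonad, -0.03 in female gonad and -11.29 in gill. Because gill is 1 of the 3 groups on the other side, a probe that is low in gill alone raises this contrast, and a difference from the gonads is not shown by it. Under the slide block the estimate for CUST_195_PI415929191 was 4.761 log2 units, against 4.957 without it. Over all other settings that tested them, the estimates nearest 0 were 4.2 log2 units for CUST_195_PI415929191 and 3.178 for CUST_3943_PI415929191, below their bounds. The count of calls went to 0 with the slide as a block, with a sex term, with the percentile over all probes, with the deposited table, without the half-body samples and at an adjusted p of 0.01. It was also 0 without any 1 of the gill, digestive gland or half-body arrays or male gonad 1, and 6 without male gonad 2.

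Male gonad was compared with gill and digestive gland. limma called 0 of 5378 probes in the fixed fit, with 116 at an unadjusted p under 0.05, where 268.9 would be expected by chance. On 10 arrays it called 16 probes from 8 sequences, all higher in male gonad than in the mean of gill and digestive gland. Of these 16, all had other tested probes of their sequence moving the same way. None of them met the rule for naming a probe, which asks every male gonad array to exceed every gill and digestive gland array. Because gill is part of the other side, a probe that is low in gill alone raises this contrast. A difference of male gonad from digestive gland is therefore not shown by it. The count was 0 with the slide as a block, a sex term, normexp, the deposited table, an adjusted p of 0.01, only the groups compared, no half-body samples or without any 1 of the gill, digestive gland, male gonad or half-body arrays, and 3 with the percentile over all probes.

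Female gonad, represented by 1 array, gave 0 called probes against gill and digestive gland with limma in both fits, with 91 probes at an unadjusted p under 0.05 in the fixed fit and 410 in the 10-array fit. In the fixed design with only the arrays of the groups compared, 26 probes were called. Between female and male gonad limma likewise called 0 probes in both fits, with 60 and 284 at an unadjusted p under 0.05. In the fixed fit 268.9 probes would be under 0.05 by chance in each contrast, so its 0 calls do not show that these tissues are alike. The median log2 difference of female gonad 1 from male gonad 2 over AM probes was -4.98 (quartiles -6.15 and -0.36), and from male gonad 1 it was 0.85 (quartiles -0.01 and 1.38).

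Larvae were compared with the 4 dissected adult tissues. limma called 0 of 5378 probes in the fixed fit, with 816 at an unadjusted p under 0.05. That count stayed 0 under 10 of 16 other settings. It was 19 with trend and robust variances, 27 with quantile normalization, 36 with normexp, 65 with each array's median and 235 with no filter. On 10 arrays 584 of 5910 probes were called, 475 higher and 109 lower in larvae, and these calls rest on larvae 2 alone. On the same arrays 51 were called with the percentile over all probes (30 higher, 21 lower), 118 with normexp (81 higher, 37 lower), 515 with each array's median (338 higher, 177 lower) and 0 with the deposited table, and 270 of the 584 passed an adjusted p of 0.01. Sequences with lower calls numbered 51, of which 10 were AJ, or 19.6% against 5.06% of those tested (Fisher's exact test, adjusted p = 0.000658). Probe CUST_11367_PI415929191 was not well above background in larvae and was at least 428-fold higher in the adult tissues (limma adjusted p = 0.0073), and its 4 other probes were all called lower in larvae. Probe CUST_11335_PI415929191 was at least 321-fold higher in the adult tissues (limma adjusted p = 0.0177), and its 3 other probes were called lower in larvae as well. The bound for CUST_11335_PI415929191 equals its own estimate. For CUST_11367_PI415929191 and CUST_11335_PI415929191 the estimates nearest 0 over the other settings were -6.637 and -6.063 log2 units, smaller in size than their bounds. These 2 are AM probes, a series with a median of -11.03 on larvae 2. Probes CUST_7497_PI415929191 and CUST_4132_PI415929191 were at least 377-fold and 170-fold higher in larvae 2, but none of the other probes of their sequences passed the filter. Both were well above background on larvae 2 alone, so they were tested only because they are high there. Across the other settings that tested them, their estimates nearest 0 were 6.058 and 5.086 log2 units, below these bounds. Among sequences with higher calls, 92.46% were EY against 76.37% of those tested, and 2.19% were AM against 16.1%. With only the probes detected in a group other than larvae, the EY shares were 89.19% against 74.55%. The AM shares there were 5.405% against 17.7%. Of the 475 higher probes, 328 were well above background on larvae 2 and on no other array. Their sibling probes, meaning other probes of the same sequences, were well above background on larvae 2 in 17.6% of cases, against 16.4% for siblings of probes dark on the other 9 arrays and 56.9% for the larval-high probes detected on other arrays too. When the filter of the 11-array fit was kept, which asks for detection on both larval arrays or on all arrays of an adult group, 36 probes were called, 6 higher and 30 lower. The lower RNA input of larvae, 200 ng against 500 ng, cannot be told apart from the stage.

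The half-body sample is the adult sample nearest to a whole animal, and larvae were compared with both half-body arrays too. limma called 0 probes in the fixed fit, with 486 at an unadjusted p under 0.05, and 578 on 10 arrays, 458 higher and 120 lower in larvae. The 10-array count was 0 with the percentile over all probes, with the deposited table and with only the groups compared, 2 at an adjusted p of 0.01, 134 with normexp, 310 with a sex term and 428 with each array's median (293 higher, 135 lower). Probe CUST_8197_PI415929191 was lower in larvae by -8.94 ± 0.74 log2 units (limma adjusted p = 0.0126), and the 1 other probe of its sequence that was tested was also called lower. Probe CUST_11367_PI415929191 was at least 248-fold higher in half-body samples (limma adjusted p = 0.019). Over the other settings its estimate nearest 0 was -5.8 log2 units, smaller in size than that bound. CUST_7497_PI415929191 and CUST_4132_PI415929191 were at least 283-fold and 128-fold higher in larvae 2, the only larval array in this fit. Both were well above background on larvae 2 alone, so they were tested only because they are high there. Their spread comes from arrays at background level, and no larval spread was measured. Across the other settings that tested them, the estimates nearest 0 were 6.247 and 5.234 log2 units, below these bounds. Kept to the filter of the 11-array fit, the count was 38, with 16 higher and 22 lower, and it was 0 without either half-body array, 303 and 319 without gill 1 and gill 2, and 373 without male gonad 1.

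Half-body samples against the dissected tissues gave 0 called probes with limma in the fixed fit, with 150 at an unadjusted p under 0.05, where 268.9 would be expected by chance. On 10 arrays 28 probes from 25 sequences were called, all higher in half-body samples. Of these calls, 9 were of probes detected on all arrays of another group, and no new fit was made on such probes. Most of the calls thus entered the test because they are high in half-body samples. Probe CUST_7084_PI415929191 was not well above background on any of the 7 arrays of dissected tissues and was at least 20.8-fold higher in half-body samples (limma adjusted p = 0.0439). Probe CUST_3423_PI415929191 was at least 14.7-fold higher under the same condition (limma adjusted p = 0.0326). No other probe of either sequence was called. Both calls were lost under most other settings, 17 and 16 of 25, and normexp lowered the estimates to 2.309 and 1.83 log2 units, below these bounds. Among the 16 calls with a tested sibling, all siblings had the same sign for 12. Siblings of the called probes were well above background on the half-body arrays in 35.57% of cases, against 36.52% of all probes. Under the slide block the 2 named probes had estimates of 6.451 and 5.755 log2 units, against 6.361 and 5.814 without it. The count of calls went to 0 with the slide as a block, a sex term, normexp, the percentile over all probes, the deposited table or an adjusted p of 0.01. It was also 0 without any 1 of the gill, digestive gland or half-body arrays or male gonad 1, and fell to 7 without male gonad 2.

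**Figure D4:**
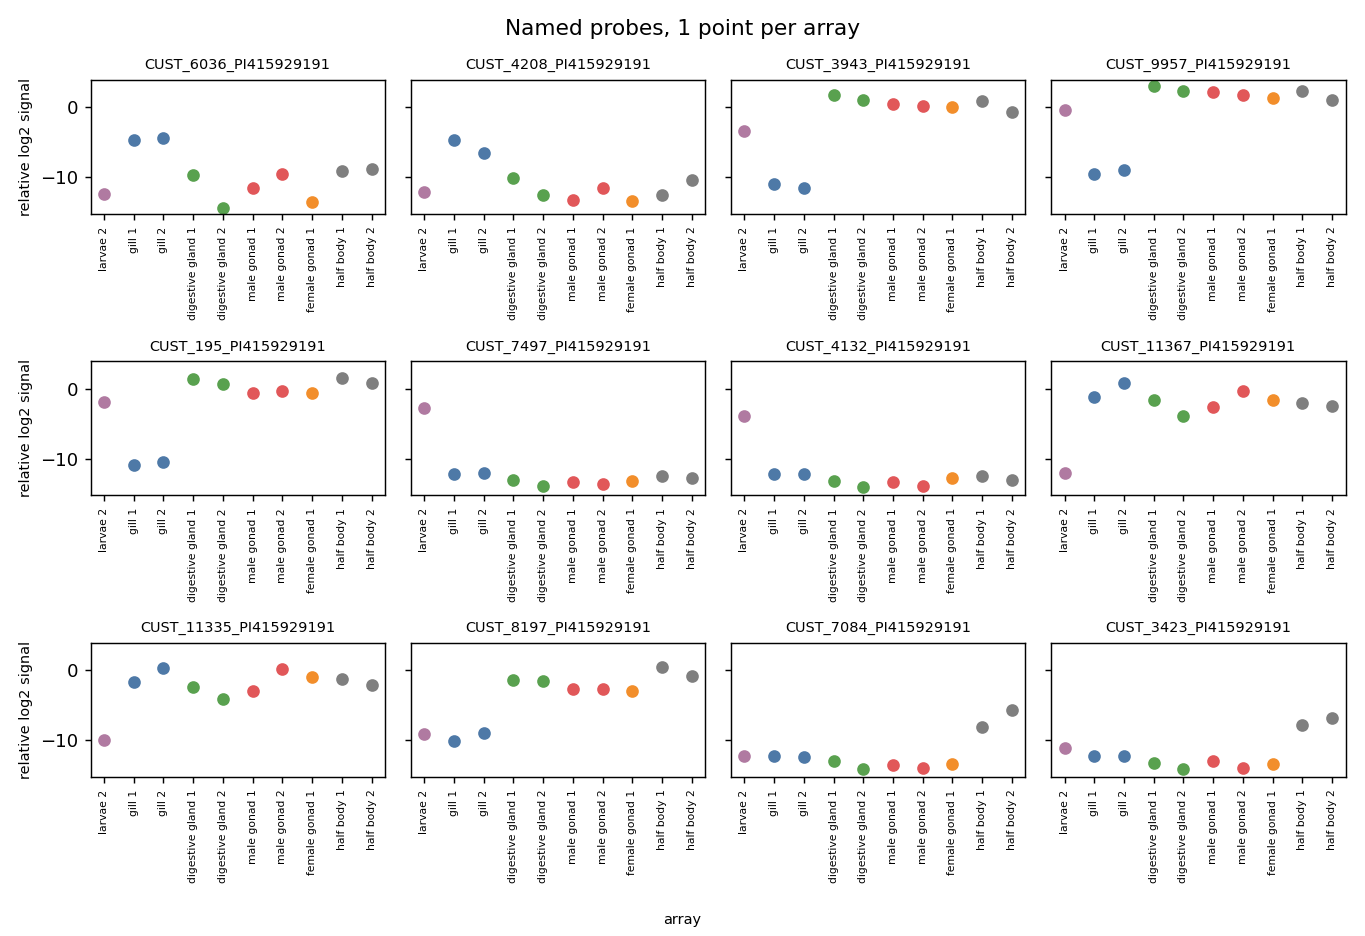
Each panel shows 1 named probe of the 10-array fit, with 1 point per array (horizontal axis) at its log2 signal relative to the array's 75th percentile of common probes (vertical axis), coloured by group. CUST_3943_PI415929191 lies at a mean of -11.29 in gill and 1.34 in digestive gland.

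Labelled sex was compared within gill, digestive gland and half-body samples, with tissue as a term. limma called 0 probes in both fits, with 14 at an unadjusted p under 0.05 in the fixed fit and 114 in the 10-array fit, where 268.9 and 295.5 would be expected by chance. Within these 6 arrays the sexes lie on different slides, so sex and slide cannot be told apart there, and a label contradicts the sex of 2 of the arrays.

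Over all groups at once, the limma F test called 4 of 5378 probes in the fixed fit and 364 of 5910 on 10 arrays. With the slide as a block, or with the deposited table, both counts were 0, and the percentile over all probes gave 57 on 10 arrays. The fixed count fell to 0 without any 1 adult array that has a partner and was 57 without larvae 1 and 1734 without larvae 2, which leaves the blank larval array alone, and the 10-array count lay between 0 and 67 when 1 array was left out. At the level of sequences with at least 3 probes, 41 of 1059 sequences were called. RXR, a nuclear receptor that pairs with other receptors, was the only gene symbol in the files. Its 6 probes were well above background on 3 to 9 of the 10 arrays, with highest signals between 15.9 and 110.8, and none was called in any contrast. Their smallest adjusted p was 0.284.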

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

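All tests in this part were chosen after the results they bear on had been seen. Larvae 1 drew attention because its control spots carry signal although its mussel probes do not. The 5 bright spike-ins, known RNAs added to every sample, had a mean log2 signal of 10.74 there, against 12.17 to 15.04 on the other arrays. They dropped by 3.14 ± 0.45 (SD) log2 units from the mean of the other arrays, while 1924 mussel probes of like brightness dropped by 13.12 ± 2.19. That difference of 9.98 argues against a loss of signal in hybridisation or scanning as the whole cause. The larval stage is also argued against, since larvae 2 had 4398 probes well above background. Little or no mussel RNA in the labelled sample may be the cause, but the spike-ins lay 1.44 log2 units below their lowest mean on any other array, which missing mussel RNA does not explain, so this stays open.

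The deposited larvae 1 column drew attention because it holds a full mussel profile. It correlated with the mean of the other columns at r = 0.983 across probes, above the 0.909 to 0.963 of the 9 columns that follow their scanner values. Against its own scanner values r was 0.28, where those 9 columns had at least 0.984, which argues against that column having been made from the same scan. What it was made from was not tested. The deposited gill 1 column, with values from -4.73 to 22.4, had r = 0.579 with its own scanner values.

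Labelled sex in gill, digestive gland and half-body samples gave 0 calls for the real split of the 6 arrays in both fits, and the highest count over the other splits was 0 as well. With 0 calls for the real split this compares nothing, and 10 splits are too few for a share under 0.05.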

How the results depend on the processing

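The alternatives to the 11-array fit were written down before the files were opened, except the 10-array fit itself, and all alternatives to the 10-array fit were chosen after the data had been seen. Normexp was planned on the mean signal and run on the median signal. A comparison not named under a setting had 0 calls with and without it, or needs samples that the setting leaves out, and the 2-fold threshold changed no count. Unless the setting itself tests fewer probes, sequences or arrays, the cause was not tested. Against the 11-array counts of 52 for gill, 4 for the F test and 0 elsewhere, the following were found. Normexp on the median signal gave 47 (2 higher, 45 lower) for gill, 36 for larvae against adult tissues, 12 for larvae against half-body samples and 5 for the F test. Quantile normalization gave 27 for larvae against adult tissues, 8 for gill and 0 for the F test. Scaling to each array's median gave 65 for larvae against adult tissues, 41 for larvae against half-body samples, 11 for gill and 0 for the F test. The percentile over the 39 probes detected on all 11 arrays gave 27 for gill and 0 for the F test. The deposited value table gave 15 for gill and 0 for the F test. No filter gave 235 (136 higher, 99 lower) for larvae against adult tissues, 131 for the F test, 104 (34 higher, 70 lower) for gill, 19 for larvae against half-body samples and 1 for female against male gonad. Testing only those 39 probes gave 0 for the F test and gill. Fitting only the groups compared gave 103 (33 higher, 70 lower) for gill, 26 (20 higher, 6 lower) for female gonad, 4 for the F test, 2 for female against male gonad and 1 for labelled sex. A replicate block gave 15 for gill and 0 for the F test. A slide block gave 0 for the F test and gill. A sex term gave 36 for gill and 0 for the F test. Leaving out the half-body samples gave 36 for gill and 0 for the F test. Trend and robust variances gave 159 (49 higher, 110 lower) for gill, 93 for the F test, 19 for larvae against adult tissues, 17 for larvae against half-body samples, 4 for male gonad and 1 for labelled sex. An adjusted p of 0.01 gave 12 for gill and 0 for the F test. The 10-array fit gave 584 (475 higher, 109 lower) for larvae against adult tissues, 578 (458 higher, 120 lower) for larvae against half-body samples, 364 for the F test, 234 (139 higher, 95 lower) for gill, 28 for half-body samples, 23 for digestive gland and 16 for male gonad. Leaving out 1 array at a time gave 0 to 133 for gill, 0 to 1734 for the F test, 0 to 3 for male gonad, 0 to 2314 for larvae against adult tissues and 0 to 2184 for larvae against half-body samples, and 0 for the rest. The highest values came from leaving out larvae 2, which makes the blank array the only larval one. Without larvae 1 the counts were 121 for gill, 57 for the F test, 51 for larvae against adult tissues and 3 for male gonad. Gill fell to 0 without either gill array, and the F test to 0 without any adult array that has a partner.

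Against the 10-array counts of 584 for larvae against adult tissues, 578 for larvae against half-body samples, 364 for the F test, 234 for gill, 28 for half-body samples, 23 for digestive gland, 16 for male gonad and 0 for female gonad, female against male gonad and labelled sex, the other settings gave the following. Here normexp on the median signal gave 154 (91 higher, 63 lower) for gill, 134 (101 higher, 33 lower) for larvae against half-body samples, 118 (81 higher, 37 lower) for larvae against adult tissues, 48 for the F test, 16 for digestive gland and 0 for male gonad and half-body samples. Quantile normalization gave 631 (519 higher, 112 lower) for larvae against half-body samples, 556 (440 higher, 116 lower) for larvae against adult tissues, 504 for the F test, 192 (104 higher, 88 lower) for gill, 18 for half-body samples, 15 for male gonad and 11 for digestive gland. Scaling to each array's median gave 515 (338 higher, 177 lower) for larvae against adult tissues, 428 (293 higher, 135 lower) for larvae against half-body samples, 201 (58 higher, 143 lower) for gill, 166 for the F test, 37 for digestive gland, 33 for male gonad and 15 for half-body samples. The percentile over all probes gave 121 (48 higher, 73 lower) for gill, 57 for the F test, 51 (30 higher, 21 lower) for larvae against adult tissues, 3 for male gonad and 0 for digestive gland, larvae against half-body samples and half-body samples. The deposited value table gave 10 for gill and 0 for the F test, digestive gland, male gonad, larvae against adult tissues, larvae against half-body samples and half-body samples. No filter gave 721 (621 higher, 100 lower) for larvae against adult tissues, 441 (365 higher, 76 lower) for larvae against half-body samples, 242 (154 higher, 88 lower) for gill, 193 for the F test, 26 for half-body samples, 18 for digestive gland and 15 for male gonad. Testing only the 3075 probes detected on all 10 arrays gave 146 (95 higher, 51 lower) for larvae against half-body samples, 124 (72 higher, 52 lower) for larvae against adult tissues, 69 (48 higher, 21 lower) for gill, 15 for the F test, 3 for digestive gland and male gonad and 0 for half-body samples. Fitting only the groups compared gave 530 (445 higher, 85 lower) for larvae against adult tissues, 364 for the F test, 153 (73 higher, 80 lower) for gill, 29 for half-body samples, 17 for digestive gland and 0 for male gonad and larvae against half-body samples. A replicate block gave 507 (394 higher, 113 lower) for larvae against adult tissues, 320 (253 higher, 67 lower) for larvae against half-body samples, 179 (90 higher, 89 lower) for gill, 63 for the F test and 0 for digestive gland, male gonad and half-body samples. A slide block gave 552 (441 higher, 111 lower) for larvae against adult tissues, 544 (422 higher, 122 lower) for larvae against half-body samples, 103 (37 higher, 66 lower) for gill and 0 for the F test, digestive gland, male gonad and half-body samples. A sex term gave 494 (406 higher, 88 lower) for larvae against adult tissues, 310 (262 higher, 48 lower) for larvae against half-body samples, 139 (61 higher, 78 lower) for gill, 47 for the F test and 0 for digestive gland, male gonad and half-body samples. Leaving out the half-body samples gave 530 (445 higher, 85 lower) for larvae against adult tissues, 148 (69 higher, 79 lower) for gill, 73 for the F test and 0 for digestive gland and male gonad. Trend and robust variances gave 608 (479 higher, 129 lower) for larvae against adult tissues, 548 (418 higher, 130 lower) for larvae against half-body samples, 530 for the F test, 186 for gill, 36 (35 higher, 1 lower) for digestive gland, 34 for half-body samples and 27 for male gonad. An adjusted p of 0.01 gave 270 (233 higher, 37 lower) for larvae against adult tissues, 79 (17 higher, 62 lower) for gill, 30 for the F test, 2 for larvae against half-body samples and 0 for digestive gland, male gonad and half-body samples. Medians per sequence, with 1059 sequences tested, gave 64 (43 higher, 21 lower) for larvae against half-body samples, 63 (47 higher, 16 lower) for larvae against adult tissues, 53 (28 higher, 25 lower) for gill, 41 for the F test, 12 for digestive gland, 5 for half-body samples and 2 for male gonad. Leaving out AM probes gave 689 (562 higher, 127 lower) for larvae against adult tissues, 676 for the F test, 655 (517 higher, 138 lower) for larvae against half-body samples, 273 (199 higher, 74 lower) for gill, 50 for half-body samples, 37 (35 higher, 2 lower) for digestive gland and 20 for male gonad. Keeping the filter of the 11-array fit gave 241 (141 higher, 100 lower) for gill, 90 for the F test, 38 (16 higher, 22 lower) for larvae against half-body samples, 36 (6 higher, 30 lower) for larvae against adult tissues, 29 for half-body samples, 26 for digestive gland and 16 for male gonad. That filter with the percentile over all probes gave 135 (60 higher, 75 lower) for gill, 55 for the F test, 16 for larvae against adult tissues, 3 for male gonad and 0 for digestive gland, larvae against half-body samples and half-body samples. That filter with quantile normalization gave 195 (103 higher, 92 lower) for gill, 95 (49 higher, 46 lower) for larvae against half-body samples, 79 for the F test, 20 for half-body samples, 17 for male gonad, 13 for digestive gland and 4 for larvae against adult tissues. With 1 array left out, counts were 128 to 311 for gill, 0 to 67 for the F test, 0 to 27 for digestive gland, 0 to 16 for male gonad, 0 to 4 for female against male gonad, 473 to 529 for larvae against adult tissues, 0 to 587 for larvae against half-body samples and 0 to 29 for half-body samples. The lowest gill counts were 128 without male gonad 1, 129 without half-body 1 and 135 without half-body 2. Male gonad went to 0 without any 1 gill, digestive gland, male gonad or half-body array, as did digestive gland and half-body samples, except for 6 and 7 without male gonad 2. Larvae against half-body samples gave 303 and 319 without gill 1 and gill 2, 373 without male gonad 1 and 0 without either half-body array. The F test gave 0 without either gill array, 45 and 67 without digestive gland 1 and 2, 55 and 63 without male gonad 1 and 2, and 38 and 42 without half-body 1 and 2. Female against male gonad gave 4 without male gonad 2.

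Of 463 values of named probes under these alternatives, 302 kept their sign and their side of the threshold, 160 kept their sign but were no longer called, and 1 turned sign, CUST_4208_PI415929191 in gill under the deposited table at -1.444 ± 3.097 (SE, limma adjusted p = 0.764). Its call was also lost under 10 other settings, and the cause of the turn was not tested. Settings without the call, and the estimate nearest 0, were 13 of 26 and 3.672 for CUST_6036_PI415929191 in gill, 1 of 26 each for CUST_3943_PI415929191 and CUST_9957_PI415929191 (-6.246 and -9.111), 18 and 16 of 26 for CUST_3943_PI415929191 and CUST_195_PI415929191 in digestive gland (3.178 and 4.2), and 17 and 16 of 25 for CUST_7084_PI415929191 and CUST_3423_PI415929191 (2.309 and 1.83). Against adult tissues they were 1 of 22 for CUST_7497_PI415929191 and CUST_4132_PI415929191 (6.058 and 5.086), and 3 and 6 of 24 for CUST_11367_PI415929191 and CUST_11335_PI415929191 (-6.637 and -6.063). Against half-body samples they were 5 and 6 of 22 for the first 2 (6.247 and 5.234), 10 of 24 for CUST_11367_PI415929191 (-5.8) and 7 of 25 for CUST_8197_PI415929191 (-7.212). In the 11-array fit they were 17 of 24 for CUST_7285_PI415929191 (4.82) and 6 of 24 each for CUST_3943_PI415929191 and CUST_9957_PI415929191 (-6.246 and -9.111). For the replicate block, differences of replicate 2 from 1 correlated across probes at 0.73 for digestive gland and male gonad, 0.4 for digestive gland and half-body samples, 0.36 for male gonad and half-body samples, 0.01 for gill with digestive gland and with male gonad, and -0.09 for gill and half-body samples. The 3 pairs that deviate together have their replicate 1 on slide 1 and their replicate 2 on slide 2, whereas gill 1 lies on slide 3, so number cannot be told apart from slide and scan day in them. The titles of both half-body samples carry the number 1, so the replicate block does not separate those 2, while the slide block does. The numbers of the half-body samples used here follow the order of the samples, so their values are no differences between labelled replicates. Both blocks take the 10-array calls of digestive gland, male gonad and half-body samples to 0. Without a block, the estimates were 4.957 for CUST_195_PI415929191 and 5.008 for CUST_3943_PI415929191 in digestive gland. In half-body samples they were 6.361 for CUST_7084_PI415929191 and 5.814 for CUST_3423_PI415929191. The blocked estimates that follow stay near these, and a block leaves less data to estimate the spread. Lost calls alone therefore do not show that slide or number carries these differences. Under the slide and replicate block, estimates of the named probes were 4.761 and 4.958 for CUST_195_PI415929191 and 4.82 and 5.087 for CUST_3943_PI415929191 in digestive gland, and 6.451 and 6.136 for CUST_7084_PI415929191 and 5.755 and 5.576 for CUST_3423_PI415929191 in half-body samples. Male gonad has no named probe, and the other calls were not looked at in this way. The gene list tests and their alternatives were not run, since the files give no gene names, and the 2-fold threshold was not applied to the F test. The F test was not run without the only array of a group. Calls on larvae in the 10-array fit rest on 1 array, and a group left with 1 array is assumed to vary like the others. Signal over background limits the rest, since at most 41.2% of probes were detected on an array.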

Other observations

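Both patterns in this part were found in the data and tested on the same data, and all of their tests were chosen after the patterns had been seen. The first is the brightness of AM probes on digestive gland 2 and male gonad 2. Slide or scan day as the whole cause is argued against, because female gonad 1 lies on the same slide and its AM probes were lower than those of male gonad 2 by a median difference of -4.98 (quartiles -6.15 and -0.36). Sex as labelled is argued against as the whole cause, because male gonad 2 exceeded male gonad 1 by a median of 5.36 (quartiles 0.47 and 7.06). One source of RNA present in different shares could produce the pattern, and it was tested in 2 ways on AM probes detected in male gonad 2 but not in gill or larvae 2. Over all 691 such probes, using those above background in both arrays, the slope against male gonad 2 was 0 for male gonad 1, 0.04 for female gonad 1, 0.26 for half-body 1 and 0.99 for digestive gland 2, where a constant share gives 1; only 39.4% to 81.9% of the probes were detected, so loss of dim probes may lower the slopes, which was not tested.

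After that result, the test was repeated on the 260 probes with a log2 signal above 11 in male gonad 2, a level picked because the first version had failed. The slopes then lay between 0.93 and 1.07, and the median offsets from male gonad 2 were -0.04 for digestive gland 2, -2.86 for half-body 2, -4.77 for half-body 1, -6.44 for digestive gland 1, -6.38 for female gonad 1 and -7.35 for male gonad 1. The widest interquartile range of an offset was 1.27 log2 units, and the offsets were not independent between arrays (r = 0.68 for half-body 1 with digestive gland 1 and -0.48 for half-body 1 with digestive gland 2). The 2 versions give different answers, so a shared source at different shares stays a possible explanation that these data do not settle. Tissue mixture, gonad state and carry-over between samples remain untested.

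The second pattern is the 328 larval-high probes detected on larvae 2 alone. They crowded on the array, with 46 in the densest of 32 blocks, against a median of 18 and a highest count of 30 in 10000 random draws (permutation p = 1e-04, the smallest the draws can give). Spots raised together in an area may therefore account for part of them. Outside that block lay 282, of which 26 fell in the densest remaining block, and no random draws were made for these 282. Siblings were above background in 17.5% of cases outside the densest block and 18.5% inside it. Crowding was not special to larvae 2. Singly detected probes on gill 1, gill 2, digestive gland 1, male gonad 2 and half-body 2 also exceeded the highest random count. Transcripts that are higher in larvae could give such calls too. Siblings of the 328 were above background in 17.63% of cases, near the 16.43% for siblings of any probe dark on the other 9 arrays, and dim siblings cannot exclude a real difference, so this stays open.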
